A study of Mus musculus with 8 samples.

How the data were processed

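Bulk RNA sequencing of mouse Achilles tendon was analysed in 8 libraries, 4 from sham-operated and 4 from partially transected tendons, grouped by the sample titles. Each deposited file holds a score per gene, which per the file headers is a normalised read count, and the authors had rounded these values to whole numbers. They are therefore not raw counts, although they are whole. In several libraries whole numbers were skipped or doubled at a regular spacing, as rounding of a count multiplied by a factor leaves. The spacing put the factors at 0.920 to 1.11. Divided by these factors, the values of the genes that had any summed to about 14000000 to 16300000 per library, which is not the number of reads sequenced. The factors of sham replicate 1 and injury replicate 1, close to 1, were only weakly determined. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.6a, StringTie 1.3.5 and edgeR 3.12 were used, with the builds mm10 and mm9 named without roles. The normalization method, the strandedness of the counting and which build was used for which step are not given in the sources used here. Of 55450 genes listed, 39703 had no value in any file, by a rule not given in the sources used here, and 15747 had values. Mitochondrially encoded genes were not among those with values.

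Because the values were normalised and rounded, a count model was not used. The plan for such values, fixed before the data were examined, was applied in its place: limma 3.58.1 in R 4.3.3 on log2(value + 1), with the prior variance following mean expression, after keeping genes with a value of at least 1 in at least 4 libraries, which removed no gene. The model held the group only. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and a subset with at least a 2-fold change was also counted. Fold changes are on the log2(value + 1) scale, which understates those of low genes. C1qtnf3 was also given an exact permutation test.

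Gene lists, 45 in number, were written down before the data were examined. They cover tendon, matrix, differentiation, signalling, inflammation and the other cell types a dissected tendon could hold. Some genes are in several lists, such as Col11a1 in the tendon, chondrogenic and fibrillar collagen lists, so the list tests are not independent. Those with at least 5 measured members (41 lists) were tested with camera of limma at a preset correlation of 0.01, and 24 were called, 17 up and 7 down. With a correlation estimated for each list none was called, and the lowest adjusted p was 0.134, so every camera call reported rests on the preset correlation. The directional test fry, which does not compare a list with other genes, called 34. List members were counted from the gene test, once over all genes and once adjusted over the list alone.

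Named genes followed a rule fixed before the data were examined: C1qtnf3; the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean of at least 5 and no overlap between the groups, without predicted or numbered transcripts; and for each list up to 3 called members with the smallest adjusted p in the direction with more calls, the first in the other direction, and the most abundant member. A gene that this rule chose is not reported here. Gene positions and exon overlaps came from GENCODE M21, with which 99.9% of tested gene identifiers matched and 96.9% matched in version. Library totals were 13596488 to 16263086 normalised counts. On simulated data for injury against sham with 15747 genes, 200 of them changed, the same test recovered 44% of genes changed 1.5-fold, 64% of those changed 2-fold, 96% of those changed 4-fold and 98% of those changed 8-fold, with 7 false calls. In the data 9402 genes were called, which makes the adjusted threshold less strict than in the simulation. The simulated shares therefore do not give the recovery for this comparison. Replicate libraries were checked for duplicates, and equal values were found for only 1.11 to 2.25% of genes in any pair of the same group.

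Alternatives covered other scalings (median-ratio and upper quartile factors, equal library totals), a pseudocount of 0.1, another filter, the replicate number as a block, the mean of skeletal muscle genes as a covariate, abundant genes left out, and each library left out in turn. After the data were seen, 4 more were added: the libraries with the most muscle for their group (sham replicate 4 and injury replicates 3 and 4) left out together, a single prior variance, a minimum mean of 50 and only genes without overlapping exons. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.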

Results

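RNA was sequenced from Achilles tendons of wild-type C57BL/6J mice, 4 after a sham operation and 4 after an injury, in 8 libraries. In the injury, an ear punch 1.5 mm wide cut through part of the tendon and left a semicircular gap of 0.75 mm in its lateral side. Tendons were taken off the adjoining soleus muscle before RNA extraction. The values are normalised read counts per gene, which summed to 13596488 to 15545903 in the sham libraries and 14568669 to 16263086 in the injury libraries. Of the 55450 genes listed, 15747 had values and were tested. The time between injury and sampling was not given in the labels used here. The labels also do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Libraries of the same group were closely alike, with Pearson correlations of log2 values across genes of 0.978 to 0.989 within sham and 0.963 to 0.986 within injury, against 0.819 to 0.921 between the groups. The first principal component of the 500 most variable genes held 88.4% of their variance and separated the groups.

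The comparison of injured with sham tendon asks how partial transection changed the tendon's transcripts, and the series title names CTRP3, the secreted C1q/TNF-related protein encoded by C1qtnf3. Injured tendon held more RNA for many matrix, metalloproteinase and cartilage genes, and less for skeletal muscle, mitochondrial and fat cell genes. C1qtnf3 itself rose 57.3-fold, from 119 ± 31.5 to 6839 ± 1478 normalised read counts (mean ± SD, n = 4 per group). The steepest rises were those of Tnn, which encodes the matrix glycoprotein tenascin-N, from 9.25 ± 2.22 to 3796 ± 1918 (331-fold), and of the collagenase gene Mmp13, from 16.5 ± 6.86 to 4925 ± 2273 (277-fold). Mmp12, encoding macrophage elastase, rose 139-fold, and Cthrc1, encoding a secreted protein with a collagen triple helix repeat, rose 122-fold, from 43.2 ± 9.43 to 5350 ± 949. The fibroblast surface gene Lrrc15 rose 81.5-fold, from 20 ± 10.6 to 1572 ± 280.

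The potassium channel subunit gene Kcns1 rose from 1.75 ± 1.26 to 304 ± 103. Rbpjl, which encodes a transcription factor best known from pancreas, rose 59.7-fold, and its exons overlap those of Matn4, itself raised 53.8-fold, by 149 bases on the other strand, so reads of either gene may have been counted for the other. Among the genes with the largest falls, Coch, which encodes the secreted matrix protein cochlin, dropped from 11070 ± 5021 to 661 ± 347 (18.0-fold lower). BC048679 was 23.0-fold lower and Fbp2, encoding muscle fructose bisphosphatase, was 19.8-fold lower. Odf3l2 was 58.6-fold lower, a value that moved to 36.2-fold without sham replicate 4 and to 98.4-fold without injury replicate 4. Bdh1, encoding mitochondrial 3-hydroxybutyrate dehydrogenase, was 28.3-fold lower (15.1-fold without injury replicate 1 and 45.3-fold without injury replicate 4). The mitochondrial carrier gene Slc25a34 was 20.9-fold lower, 10.7-fold without injury replicate 1 and 34.4-fold without injury replicate 4. Ostn, which encodes the muscle-secreted peptide musclin, was 18.7-fold lower, or 11.4-fold without injury replicate 1. In each of these genes, every injury library lay on the same side of every sham library, as the naming rule required.

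At an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment, 9402 of the 15747 genes differed, 4481 of them higher and 4921 lower in injured tendon. A change of at least 2-fold was found for 3335 genes, 1250 higher and 2085 lower. The groups did not overlap for 8755 genes (55.6%), where chance gives 2.86%. Scaling every library to the same total moved the median log2 fold change of all genes from −0.021 to −0.112. A fit with the mean of skeletal muscle genes as a covariate left 3730 genes, of which 3414 were also called without it, and ended 51 of the calls on the 191 genes chosen for naming. Among these, Odf3l2 went to a log2 fold change of −2.89 from −5.87, Bdh1 to −1.08 from −4.82, Slc25a34 to −0.12 from −4.39 and Ostn to −1.07 from −4.23. A lost call is not a lost change, since other genes lost it with a fold change as large as before. Exons of 5039 tested genes overlapped those of another tested gene, and with these left out 6497 genes differed.

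C1qtnf3 (ENSMUSG00000058914.12) is a protein-coding gene on the forward strand of chromosome 15 at 10952332 to 10980150 in GENCODE M21. Its 4 sham libraries held 109, 119, 87 and 162 normalised read counts, and its 4 injury libraries held 5283, 8742, 7141 and 6191. The log2 fold change was 5.84 (SE 0.20), with an adjusted p of 2.92e-07 in limma with Benjamini-Hochberg adjustment, and it ranked 9 among all tested genes by log2 fold change. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 samples allow. Of 15 measured members of the C1q and TNF-related protein list, 9 rose, 5 fell and 1 did not pass, with the same counts adjusted over the list alone. Under the muscle covariate 4 rose and 2 fell. The list as a whole was not called by camera (adjusted p = 0.189, and adjusted p = 0.541 with an estimated correlation).

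Its relatives C1qtnf6 and C1qtnf1 rose as well, from 888 ± 354 to 7576 ± 1270 (8.90-fold) and from 523 ± 89.6 to 3015 ± 404 (5.78-fold). C1qtnf2 rose 5.87-fold, from 195 ± 14.2 to 1154 ± 165. Adipoq, which encodes the fat cell hormone adiponectin of the same protein family, was 7.15-fold lower, at 2013 ± 617 in sham and 283 ± 104 in injured tendon. The exons of C1qtnf1 overlap those of an antisense gene over 642 bases.

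**Figure D1:**
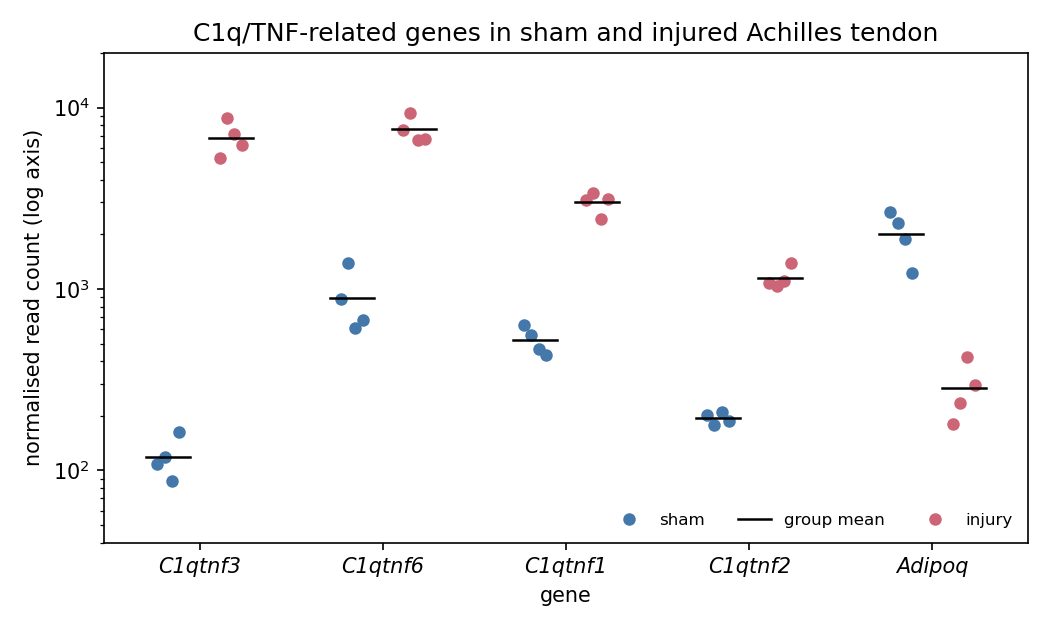
Normalised read counts (vertical axis, log scale) of C1qtnf3, C1qtnf6, C1qtnf1, C1qtnf2 and Adipoq in sham (blue) and injured (red) Achilles tendon, with 1 point per library, 4 libraries per group and a line at each group mean. The injury values of C1qtnf3 lie between 5283 and 8742 and its sham values between 87 and 162.

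Genes for the extracellular matrix rose broadly. Of 38 measured matrix glycoproteins and matricellular proteins, 30 rose, none fell and 8 did not pass, while adjusted over the list alone 30 rose and 2 fell (camera adjusted p = 4.07e-11, and adjusted p = 0.134 with an estimated correlation). Over all genes, 1 of them fell without sham replicate 4 or without injury replicate 3, 2 without injury replicate 4, and 3 with equal totals or without the 3 libraries with the most muscle for their group (sham replicate 4 and injury replicates 3 and 4). Fbn2, encoding fibrillin-2, rose 29.3-fold, from 66.8 ± 10.7 to 2004 ± 457, and Postn, encoding periostin, rose 10.1-fold, from 1363 ± 193 to 13620 ± 1066. Sparc, encoding a collagen-binding protein and the most abundant member, went from 170900 ± 47680 to 464200 ± 30480 (adjusted p = 0.0234 in limma). Its call was lost without any 1 of sham replicate 3 and injury replicates 2, 3 and 4, with adjusted p of up to 0.0899 in these fits. The replicate number as a block ended it too (adjusted p = 0.1065). So did the muscle covariate (adjusted p = 0.126) and leaving out sham replicate 4 and injury replicates 3 and 4 together (adjusted p = 0.0536). Its log2 fold change of 1.48 (SE 0.48) was 1.41 and 1.35 in these last 2 fits, and 1.35 to 1.65 in the fits without 1 library. The call of Sparc was thus lost with little change in the size of its rise. Over all alternatives the adjusted p of Sparc was 0.000249 to 0.126. Its groups did not overlap, with 128421 to 238797 in sham and 430329 to 496437 in injury libraries.

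Of 11 fibrillar collagen genes, 9 rose and 2 did not pass (10 rose adjusted over the list alone; camera adjusted p = 4.28e-06, and adjusted p = 0.326 with an estimated correlation). Col11a1 rose 9.54-fold to 34530 ± 4090, Col5a1 rose 6.25-fold to 38360 ± 5381 and Col5a2 rose 5.51-fold to 54630 ± 6390. The members that did not pass were the collagen I genes, the most abundant genes of tendon. Col1a2 had 403600 ± 126000 in sham and 1100000 ± 79670 in injured tendon (log2 fold change 1.49, SE 0.79, adjusted p = 0.133 in limma), and Col1a1, chosen after its values were seen, had 293800 ± 120700 and 956700 ± 105900 (adjusted p = 0.0524 in limma). The groups did not overlap for Col1a2, with 290215 to 583679 in sham and 1001987 to 1186950 in injury libraries. Its missing call rests on the prior variance that followed mean expression. With a prior variance shared by all genes Col1a2 passed (adjusted p = 0.000376). It also passed with a minimum mean of 50 (adjusted p = 0.0467) and among genes without overlapping exons (adjusted p = 0.0376). Over all its alternatives the adjusted p lay between 0.000376 and 0.348. The 11 genes held 5.43 ± 1.80% of all normalised counts in sham and 16.4 ± 1.10% in injured tendon (n = 4 each).

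Of 26 other collagens, 15 rose, 6 fell and 5 did not pass (7 fell adjusted over the list alone; camera adjusted p = 0.00748, and adjusted p = 0.465 with an estimated correlation). Col12a1, a collagen of fibril surfaces, rose from 3773 ± 703 to 41740 ± 8124 and Col8a1 from 552 ± 89.9 to 6128 ± 1140, while Col4a3, a basement membrane collagen, fell to 9.75 ± 5.12 from 61.8 ± 13.1. Enzymes and chaperones of collagen processing and crosslinking moved with them: 24 of 27 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.01e-07, and adjusted p = 0.326 with an estimated correlation). The lysyl oxidase gene Loxl1 rose 7.43-fold, P3h1, a collagen prolyl hydroxylase, rose 2.98-fold and the collagen chaperone Serpinh1 rose 2.92-fold to 21620 ± 2534. The transglutaminase gene Tgm2 was 1.83-fold lower. Among 21 proteoglycan genes, 13 rose, 2 fell and 6 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.00188, and adjusted p = 0.449 with an estimated correlation). Lum, encoding lumican, rose 12.5-fold, from 1795 ± 182 to 22470 ± 3163, Aspn, encoding asporin, rose 7.97-fold, and Spock3 was 4.01-fold lower. Calls lost under the muscle covariate were those of Col4a3 (log2 fold change −1.82, from −2.63), Tgm2 (−0.40, from −0.87) and Spock3, which was still 3.62-fold lower. The counts that fell became 2 other collagens, 1 processing gene and 1 proteoglycan gene in that fit, and 4 proteoglycan genes without sham replicate 4 and injury replicates 3 and 4 together.

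Matrix-degrading proteases rose in parallel. Of 35 metalloproteinase genes, 25 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.29e-07, and adjusted p = 0.134 with an estimated correlation). Mmp14, encoding a membrane-bound metalloproteinase, rose 12.5-fold, from 1082 ± 79.9 to 13530 ± 632, and the gelatinase gene Mmp2 rose 11.4-fold, from 6024 ± 545 to 68590 ± 6370. Mmp11 was 3.91-fold lower. Its exons overlap those of Chchd10 by 155 bases on the other strand. Chchd10 was more abundant and fell further (log2 fold change −3.32 against −1.97), so its reads may have been counted for Mmp11. The 4 metalloproteinase genes that fell became 1 under the muscle covariate. Protease inhibitors and fibrinolysis genes went both ways, with 7 of 12 higher and 3 lower, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.05 after rounding, and adjusted p = 0.472 with an estimated correlation). The metalloproteinase inhibitor Timp1 rose 4.37-fold and Timp2 rose 4.10-fold to 87240 ± 8117, whereas Timp4 was 12.3-fold lower, falling to 84.2 ± 28.7 from 1062 ± 376. That list passed without any 1 of sham replicates 1 and 3 and injury replicates 1, 2 and 3, and the adjusted p over the 8 fits without 1 library was 0.0401 to 0.0658. It also passed with equal totals (adjusted p = 0.0231) and with the replicate number as a block (adjusted p = 0.0308). Without sham replicate 4 and injury replicates 3 and 4 together it passed too (adjusted p = 0.0494). Over all alternatives its adjusted p was 0.000342 to 0.472.

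Tendon and cartilage genes both increased. Of 20 genes known from tendon cells, 15 rose, 1 fell and 4 did not pass (16 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.01e-07, and adjusted p = 0.269 with an estimated correlation). Tnc, encoding tenascin-C, rose 12.4-fold, from 1286 ± 266 to 15780 ± 1790, and Eya1 was 4.76-fold lower. Of 18 chondrogenic genes, 14 rose, 2 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 9.31e-05, and adjusted p = 0.269 with an estimated correlation). Acan, encoding the cartilage proteoglycan aggrecan, rose 20.6-fold, from 469 ± 96.9 to 9713 ± 2152, and Matn4, encoding matrilin-4, rose from 158 ± 23.6 to 9177 ± 4124. Sox6, a transcription factor gene of cartilage, was 2.09-fold lower, and the most abundant member, Chad, had 108000 ± 20930 in sham and 80130 ± 9460 in injured tendon (adjusted p = 0.213 in limma). Both Eya1 and Sox6 lost their calls with the muscle covariate, under which the log2 fold change of Eya1 was −0.46, from −2.25, that of Sox6 turned to 0.04, and no gene of either list fell. The 2 chondrogenic genes that fell became 1 without any 1 of sham replicates 1 and 3 and injury replicates 2 and 3, and also without sham replicate 4 and injury replicates 3 and 4 together.

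Genes of bone formation and mineralization split, with 5 of 13 higher and 6 lower, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.965, and adjusted p = 0.975 with an estimated correlation). Alpl, encoding tissue-nonspecific alkaline phosphatase, was 4.19-fold lower, at 236 ± 43.1 in sham and 57 ± 17.4 in injured tendon, and Ibsp, encoding bone sialoprotein, was 9.90-fold lower. Enpp1, whose product makes the mineralization inhibitor pyrophosphate, rose 5.94-fold, from 745 ± 86.8 to 4427 ± 407. Most of the exon length of Phospho1, 4.48-fold lower, is shared with other genes. Of 16 genes used to mark tendon stem and progenitor cells, 7 rose, 3 fell and 6 did not pass, likewise adjusted over the list alone, and the list was not called (camera adjusted p = 0.103, and adjusted p = 0.543 with an estimated correlation). Cd44 rose 2.36-fold and Bgn, encoding biglycan, rose 5.38-fold to 118400 ± 11490, while Nes, encoding nestin, was 2.69-fold lower. With the muscle covariate, Nes had a log2 fold change of −0.26 and was not called, Phospho1 was not called (−1.29, from −2.16), 3 bone formation genes rose, and the progenitor list as a whole passed (adjusted p = 0.0094, in a range of 0.000332 to 0.543 over all alternatives). The 3 progenitor genes that fell became 1 without sham replicate 1, 5 without injury replicate 4 or with equal totals, 6 without sham replicate 4 and injury replicates 3 and 4 together and 0 under the muscle covariate.

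**Figure D2:**
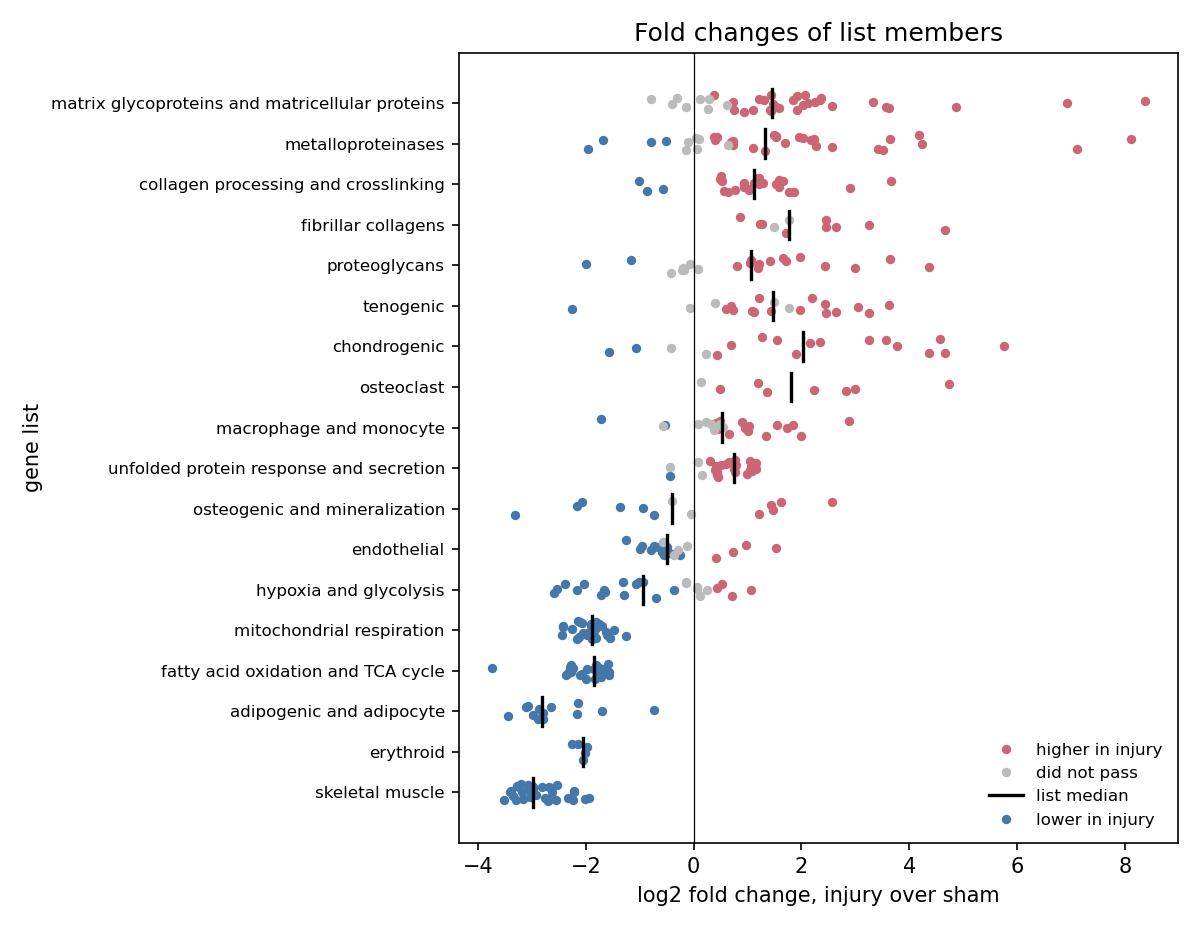
Log2 fold change (injury over sham, horizontal axis) of each measured member of 18 gene lists (vertical axis), with a point per gene coloured red where it was higher in injured tendon, blue where it was lower and grey where it did not pass, and a black bar at each list's median. The median was 2.03 for chondrogenic genes and −2.98 for skeletal muscle genes.

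Skeletal muscle, energy metabolism and fat cell genes were lower in injured tendon. All 33 measured skeletal muscle genes fell, with the same count adjusted over the list alone (camera adjusted p = 2.21e-07, and adjusted p = 0.541 with an estimated correlation). The actin gene Acta1 dropped from 250000 ± 58420 to 38250 ± 26630 (8.06-fold lower), Mb, encoding myoglobin, was 9.74-fold lower and Cox6a2, a muscle form of a respiratory chain subunit, was 10.7-fold lower. These 33 genes held 9.90 ± 2.45% of all counts in sham and 1.52 ± 1.06% in injured tendon (n = 4 each), with library values of 9.15, 8.98, 7.97 and 13.5% in sham and 0.45, 0.83, 2.05 and 2.73% after injury. All 8 muscle regeneration genes also fell, the same adjusted over the list alone (camera adjusted p = 0.00545, and adjusted p = 0.472 with an estimated correlation), among them Myod1, a master regulator of muscle cell fate, which was 5.20-fold lower, and Myf6, 7.91-fold lower.

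All 31 nuclear genes of mitochondrial respiration fell (camera adjusted p = 4.07e-11, and adjusted p = 0.465 with an estimated correlation), as did all 23 genes of fatty acid oxidation and the citric acid cycle (camera adjusted p = 8.32e-09, and adjusted p = 0.465 with an estimated correlation). Both counts were the same adjusted over the list alone, and both lists moved together with the muscle share of 9.90 ± 2.45% in sham and 1.52 ± 1.06% in injured tendon. Ndufs7, a complex I subunit gene, was 4.16-fold lower, at 2534 ± 390 and 617 ± 154, and Atp5b, of ATP synthase, was 3.73-fold lower. Acadm, encoding an acyl-CoA dehydrogenase, dropped from 5436 ± 661 to 1187 ± 371 (4.72-fold lower) and Idh2 was 5.18-fold lower. Of 25 hypoxia and glycolysis genes, 4 rose, 15 fell and 6 did not pass, likewise adjusted over the list alone, and the list was not called (camera adjusted p = 0.052, and adjusted p = 0.653 with an estimated correlation). Vegfa was 3.15-fold lower and the glycolytic enzyme gene Aldoa was 5.25-fold lower, while Hif1a rose 2.08-fold. Calls were lost under the muscle covariate for Aldoa (log2 fold change −0.27, from −2.39), Atp5b (−0.66, from −1.90), Myod1 (−0.69, from −2.38) and Myf6 (−0.31, from −2.98). In that fit 1 hypoxia gene fell and no muscle regeneration gene fell, while 30 of the respiration genes and 18 of the fatty acid oxidation and citric acid cycle genes still did. The hypoxia list passed without sham replicate 3 (adjusted p = 0.0481) and without injury replicate 4 (adjusted p = 0.0145), in a range of 0.0145 to 0.0742 over the 8 fits without 1 library. It passed too with the replicate number as a block (adjusted p = 0.026) and without sham replicate 4 and injury replicates 3 and 4 together (adjusted p = 0.00296). Its median turned to 0.039 with the muscle covariate (adjusted p = 0.838), and over all alternatives its adjusted p was 0.00296 to 0.838. With that covariate the muscle regeneration list was not called (adjusted p = 0.166, in a range of 0.000619 to 0.472 over all alternatives). The skeletal muscle genes form the covariate, so that fit cannot test them.

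All 14 fat cell genes fell, the same adjusted over the list alone (camera adjusted p = 6.19e-06, and adjusted p = 0.465 with an estimated correlation). Cidec and Plin4, which encode lipid droplet proteins, were 7.91-fold and 8.59-fold lower, and Lpl, encoding lipoprotein lipase, dropped from 19720 ± 1550 to 4612 ± 1520. Under the muscle covariate 9 of them fell. All 5 red blood cell genes fell as well, likewise adjusted over the list alone (camera adjusted p = 0.00687, and adjusted p = 0.411 with an estimated correlation), with the globin gene Hba-a1 at 2704 ± 970 in sham and 622 ± 109 in injured tendon.

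**Figure D3:**
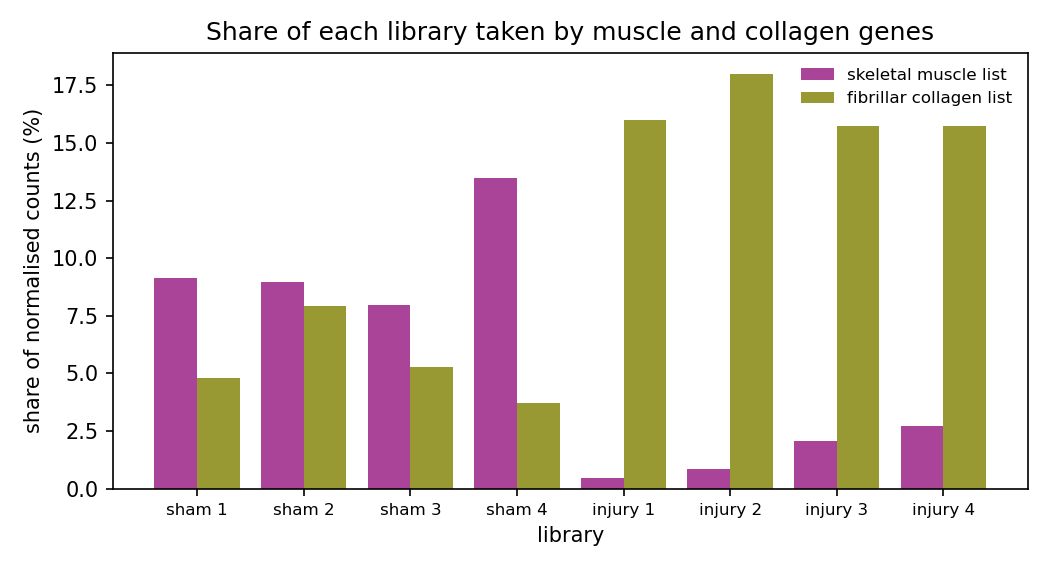
Share of all normalised counts (vertical axis, percent) taken by skeletal muscle genes and by fibrillar collagen genes in each of the 8 libraries, with sham and injured tendon as separate groups. Muscle genes held 7.97 to 13.5% in sham and 0.45 to 2.73% in injured libraries, while fibrillar collagens held 3.70 to 7.94% and 15.7 to 18.0%.

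Many genes of macrophages and bone-resorbing cells were higher in injured tendon. Of 26 macrophage and monocyte genes, 17 rose, 2 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.000577, and adjusted p = 0.541 with an estimated correlation). The lysozyme gene Lyz2 rose 2.92-fold, from 6906 ± 835 to 20070 ± 1585, and Gpnmb, a glycoprotein gene of lipid-laden macrophages, rose 7.34-fold, while Cd163, a haemoglobin scavenger receptor of resident macrophages, was 3.28-fold lower. With the muscle covariate the macrophage list was not called (adjusted p = 0.0534, in a range of 6.11e-05 to 0.541 over all alternatives), its mean log2 difference went from 0.70 to 0.33 (95% interval −0.69 to 1.35), and 8 of its genes rose. The 2 macrophage genes that fell became 1 in the fits without any 1 of sham replicates 1, 2 and 3 and injury replicates 2, 3 and 4, and 4 without sham replicate 4 and injury replicates 3 and 4 together. Of 8 osteoclast genes, 7 rose and 1 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.000467, and adjusted p = 0.134 with an estimated correlation). Atp6v0d2, encoding a proton pump subunit, rose 26.6-fold, from 10.8 ± 2.22 to 316 ± 83.0. Ctsk, encoding the collagen-degrading protease cathepsin K, rose 7.98-fold, from 1564 ± 361 to 12360 ± 1740. Ctsk is also in the list of tendon stem and progenitor cell genes, so its rise does not mark osteoclasts alone.

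Of 22 inflammatory cytokine and receptor genes, 13 rose, 2 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.465 with an estimated correlation). The receptor genes Il13ra1 and Il4ra rose 2.50-fold and 2.12-fold. Among 18 chemokine genes, including receptors, 10 rose, 1 fell and 7 did not pass (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0286, and adjusted p = 0.465 with an estimated correlation). Cxcr4 rose 3.70-fold, from 77.2 ± 9.98 to 289 ± 42.1. The fall of Cxcl9 (log2 fold change −1.09, adjusted p = 0.0237 in limma) was no longer called with the muscle covariate, where it was larger (−1.65), or without any 1 of sham replicates 1, 2 and 3 (−0.99, −0.99 and −1.05), over an adjusted p range of 0.00784 to 0.0648 in the fits without 1 library. Of 17 complement genes, 10 rose, 2 fell and 5 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.541 with an estimated correlation), with C3ar1 up 2.60-fold and Cfd, a complement factor gene of fat cells, 6.27-fold lower. Without sham replicate 4 and injury replicates 3 and 4 together, a choice made after seeing the data, the chemokine and complement lists no longer passed (adjusted p = 0.103 and adjusted p = 0.0843, in ranges over all alternatives of 0.00144 to 0.465 and 0.0127 to 0.541). The complement list was also not called with the muscle covariate (adjusted p = 0.0674), although its median log2 fold change hardly moved (0.41, from 0.42). In that fit 6 complement genes rose and 1 fell, 7 cytokine genes rose and 0 fell, and 3 chemokine genes rose. In the fit without those 3 libraries 4 complement genes fell, and 6 chemokine genes rose and 3 fell. The 2 complement genes that fell became 1 without any 1 of sham replicates 1, 2 and 3 and injury replicates 1 and 3. The single chemokine gene that fell became 0 without any 1 of sham replicates 1, 2 and 3, and 2 without sham replicate 4, and the 2 cytokine genes became 1 without injury replicate 2.

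Genes of the secretory pathway rose, and those of growth factor pathways were divided. Of 27 genes of the unfolded protein response and secretion, 23 rose, 1 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 3.01e-07, and adjusted p = 0.422 with an estimated correlation). Sec61a1, of the channel into the endoplasmic reticulum, rose 2.23-fold, the chaperone gene Calr rose 2.08-fold to 10240 ± 987, and the stress transcription factor gene Ddit3 was 1.36-fold lower, a call lost without sham replicate 4 and injury replicates 3 and 4 together (log2 fold change −0.19, from −0.44). The count of 1 that fell became 2 without sham replicate 4. Of 36 TGF-beta and BMP pathway genes, 16 rose, 13 fell and 7 did not pass, and the list was not called (camera adjusted p = 0.212, and adjusted p = 0.613 with an estimated correlation). Fstl1 rose 4.44-fold to 21980 ± 802, the receptor gene Tgfbr2 rose 2.34-fold and Nog, encoding the BMP antagonist noggin, was 4.94-fold lower. Under the muscle covariate 10 members of this list rose and 5 fell.

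In the Wnt and hedgehog pathways 16 of 31 genes rose and 7 fell (camera adjusted p = 0.103, and adjusted p = 0.541 with an estimated correlation), with the receptor gene Fzd2 up 3.60-fold and the antagonist gene Wif1 3.49-fold lower. That list passed with equal totals (adjusted p = 0.0469) and with the muscle covariate (adjusted p = 0.0237), in a range of 0.000877 to 0.541 over all alternatives. In the PI3K-AKT and IGF pathway 11 of 28 rose and 7 fell (camera adjusted p = 0.299, and adjusted p = 0.541 with an estimated correlation), including a 2.40-fold rise of Igf1. Of 22 fibroblast growth factor and PDGF genes, 12 rose and 7 fell (camera adjusted p = 0.267, and adjusted p = 0.613 with an estimated correlation). Fgf18 rose 4.09-fold, Pdgfrb rose 2.40-fold and Fgf1 was 3.77-fold lower. Under the muscle covariate 10 genes of the Wnt list rose and 2 fell, 7 of the PI3K list rose and 1 fell, and 7 of the growth factor list rose and 2 fell. For these 3 lists and the TGF-beta list, the counts were the same adjusted over the list alone.

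Of 33 cell cycle genes, 14 rose, 2 fell and 17 did not pass (13 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.543 with an estimated correlation). E2f1 rose 2.37-fold, from 79.8 ± 26.1 to 182 ± 11.8, and Rrm2, for nucleotide synthesis, rose 1.70-fold. Cdkn1a, which encodes an inhibitor of the cell cycle, rose 1.46-fold. Ube2c, 9.09-fold lower with 48890 ± 16940 in sham, overlaps the muscle troponin gene Tnnc2 by 592 exon bases on the opposite strand. With the muscle covariate 2 members rose and 1 fell, and calls were lost for Ube2c (log2 fold change −0.32, from −3.18), whose neighbour Tnnc2 is a gene of the covariate, for E2f1 (0.81, from 1.24) and for Rrm2, whose rise was larger (1.03, from 0.77). The count of 14 raised members became 9 without sham replicate 4, 7 without injury replicate 3 and 3 without sham replicate 4 and injury replicates 3 and 4 together, where the list no longer passed (adjusted p = 0.114, over a range for all alternatives of 0.00296 to 0.543).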

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

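The fit with a muscle covariate and the test without abundant genes were planned before their results were seen, and the other tests in this part, the splits of the libraries included, were chosen afterwards. Among the 35 ways to split the 8 libraries into 4 and 4, only 1, the real one, called as many genes as the 9402 found. The highest of the others called 1 gene. Every other split mixes sham and injury libraries, which widens the spread within each side and holds its count down. The real split ranked first of 35, the most that so few splits can show. The test cannot separate the injury from another difference between the groups. The 3335 genes with a 2-fold change were likewise matched by 1 split, the real one, and the highest other count was 1. For the number of gene lists called with a preset correlation, 5 of 35 splits reached the real value of 24 and the highest other split called 26. The others among these exchange a single library between the groups, so they still hold much of the group difference. Splits with 2 libraries of each group on a side called 1 to 15 lists. The splits therefore cannot decide whether chance gives as many lists.

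The joint fall of 54 mitochondrial respiration and fatty acid oxidation genes was set against 2 technical explanations. Their mean log2 value fell by 1.96, and within the groups it followed the mean of the skeletal muscle genes over the 8 libraries (r = 0.95, rho = 0.98, exact permutation p = 0.00521 over 576 rearrangements for r). With the muscle mean as a covariate the adjusted injury effect was −0.87 (95% interval −1.34 to −0.39), which reaches to both sides of the preset bound of −0.98, and muscle and group were themselves correlated at −0.87. Less muscle in the injured samples therefore may account for part of the fall or for most of it, and a change within tendon cells cannot be told apart from it because muscle and group go together. Only the authors' scaling of whole libraries is argued against, since no other scaling moved the median of all genes beyond −0.112. These scalings were computed from the normalised values themselves, with factors of 0.911 to 1.09 per library. A normalization that treats genes unequally could not be tested with them.

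The rise of 82 matrix, collagen processing and chondrogenic genes, by a mean of 1.63 (SE 0.06) on the log2 scale, was weighed in the same way. If a lower muscle share raised every other cell type alike, endothelial genes would rise too, but their mean log2 difference was −0.30. The matrix, collagen processing and chondrogenic genes exceeded that list by 1.93 (95% interval 1.72 to 2.14), which argues against such even dilution only. The gap includes the endothelial fall itself. Within the groups the endothelial mean did not follow the muscle mean (r = 0.05). With the muscle covariate the endothelial difference was −0.29 (95% interval −0.78 to 0.20). That interval is wide, so whether endothelial cells were lost along with muscle stays undecided. With the muscle covariate the rise was 1.73 (95% interval 1.41 to 2.05). After muscle, erythroid and fibrillar collagen genes were taken out and the rest rescaled, the 79 genes left rose by 1.52 (SE 0.07). That step moved the median log2 fold change of the tested genes only from −0.021 to −0.067. Muscle genes held 9.90% of counts in sham and 1.52% in injured tendon, and fibrillar collagens 5.43% and 16.4%. Because these shares largely offset each other, rescaling could hardly change the rise. The test therefore cannot decide whether a few genes taking most of the counts account for it. A response of the tendon to the injury is consistent with these values as a hypothesis, and the number and kind of cells in the samples stay open as untested.

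Several genes moved with a gene whose exons overlap theirs. The ratio of Ube2c to the overlapping troponin gene Tnnc2 had a highest over lowest value of 1.07 across the 8 libraries, and across 2640 pairs with exons overlapping on opposite strands the fold changes correlated at 0.77, against 0.18 for 2401 neighbours under 10 kb apart without overlap (both across genes, which are not independent replicates). Reads counted for both genes are therefore a likely source of part of these calls. Apart from overlaps, 21 adjacent pairs both rose at least 4-fold, where random placement gave a mean of 3.6 and a 95th percentile of 7 (permutation p = 1e-04, the smallest that 10000 placements can give), so chance order is argued against. Adjacent here means next in order among the tested genes, with gaps of 160 to 974250 bases, so many pairs were not close. Some pairs share a gene, and some are of the same gene family, such as Mmp13, Mmp12 and Mmp3. What joins these neighbours, such as family membership, shared regulation or transcripts running on from a raised gene, was not tested.

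Single libraries stood apart from the other 3 of their group for 33 of 472 groups of values, with a gap beyond Dixon's 95% critical value, where chance gives 23.6. Many concerned sham replicate 4, the library with the most muscle (13.5%): Odf3l2 at 525 against 66 to 99, Alpl at 301, Tpm2 at 91110, Egfr at 972, Fgf1 at 1309, Il4ra at 468, Des at 50260, Chrna1 at 340, Myf6 at 1151, Sema3c at 1494, Aldoa at 103600, Ramp1 at 1128 and Ntf5 at 54 normalised read counts. Its mean log2 value was 8.284 for the chondrogenic list and 7.926 for the muscle regeneration list. Chance alone sets apart about 1 in 20 groups. In the other sham libraries, replicate 2 had 9670 for Serpinh1, and replicate 3 had 231 for Ms4a7 and 318 for Lmod1.

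Among the injury libraries, replicate 1 had 4995 normalised read counts for Loxl1, 128 for Oasl2, 914 for Egfl7 and 4672 for Rpl13. Injury replicate 2 had 9126 for Col8a2 and 2106 for P3h1, a fibrillar collagen share of 18.01%, and a mean log2 of 9.736 for the endothelial list. Injury replicate 3 had 3817 for Enpp1 and mean log2 values of 8.522 for the osteogenic and 6.115 for the keratinocyte list. Injury replicate 4 had 9 for Odf3l2, 1399 for C1qtnf2, 209 for Cd163 and 458 for Sbsn.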

How the results depend on the processing

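The fit without the 3 libraries with the most muscle for their group (sham replicate 4 and injury replicates 3 and 4), the single prior variance, the minimum mean of 50 and the fit on genes without overlapping exons were chosen after seeing the data, and the other alternatives before. The count of 9402 genes was 9423 with median-ratio factors, 9369 with upper quartile factors, 8981 with equal totals (38.2% of them higher, 47.7% in the original scaling), 9395 with a pseudocount of 0.1, 9127 without muscle, erythroid and fibrillar collagen genes, 9320 with a single prior variance, 8269 above a mean of 50, 6497 without overlapping genes and 8582 (3871 higher, 4711 lower) without those 3 libraries. The muscle covariate cut it to 3730 (2139 higher, 1591 lower; 1678 at least 2-fold) and moved 47 of 88 list member counts by more than 1.5 times, equal totals moved 5, the block 3 and leaving out the 3 libraries 20. Leaving out each library gave 8641 to 9013 genes, 4072 to 4307 higher, 4531 to 4788 lower and 3098 to 3467 at least 2-fold, with 24 to 26 lists. All genes called both here and in each alternative had the same sign, except 11 of 3414 with the covariate. The log2 fold change of C1qtnf3 was 5.70 to 6.00 without 1 library and 6.24 with the covariate, and its call held under all 20 alternatives. An estimated correlation left 0 lists (lowest adjusted p 0.134) and fry called 34. With the replicate number as a block, 9742 genes (4635 higher, 5107 lower; 3351 at least 2-fold) and 25 lists were called and C1qtnf3 stayed at 5.84. The block ended the calls on Sparc, Mx1, Rpl13 and the myofibroblast list, added Irf1 and the protease inhibitor and hypoxia lists, and changed no other call on a named gene or list. Same-numbered libraries deviated together with correlations of 0.25, 0.28, −0.01 and 0.49. Sham replicates 1, 2 and 4 correlated best with the injury library of their own number and sham replicate 3 with injury replicate 1 (0.26). The 2 libraries numbered 4 also held the most muscle of their groups (13.5% in sham and 2.73% in injury). Sham replicate 4 correlated at −0.43, −0.27 and 0.20 with injury replicates 1, 2 and 3, whose muscle shares were 0.45, 0.83 and 2.05%. Muscle content may therefore account for its match, and whether the samples were paired stays open. Over all alternatives, named genes kept direction and side of the threshold in 3639 cases and turned in 13, while the call was lost in 100 cases and gained in 9. No gene was called where it turned. With the covariate the turned values were Sox6 0.0443, Abcc9 0.18, Sox10 0.0892, Prg4 0.0684, Ntf5 0.11, Nrp1 0.27 and Cxcl12 −0.13. The covariate also turned the medians of the pericyte (0.21), Schwann cell (0.23) and hypoxia (0.039) lists. Cxcl12 (0.03) turned to −0.0572 with equal totals, −0.0138 without the abundant genes and as low as −0.0265 in a range up to 0.0815 without 1 library. Foxp3 was −0.15 to 0.0665 without 1 library and 0.0612 without the 3 libraries. The direction of the test turned for the osteogenic list with fry (median −0.39, adjusted p = 0.0483, the only turned list that was called), equal totals (−0.48) and without 1 library (−0.64 to −0.0589), for the mast cell list (−0.16 to 0.50 without 1 library, −0.51 without the 3) and for the interferon list (0.0437 to 0.28, and −0.0399). The cause was not tested. The other filter, on abundance relative to the library total, removed no gene and moved nothing, and DESeq2 and limma-voom were not run because they need counts.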

Other observations

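No test in this part was planned to explain a result, and the names of single genes follow the rule fixed before the data were examined. Of 21 endothelial genes, 4 rose, 13 fell and 4 did not pass (4 rose and 15 fell adjusted over the list alone; camera adjusted p = 0.0452, and adjusted p = 0.577 with an estimated correlation). Sox17, a transcription factor gene of arterial endothelium, was 2.40-fold lower and the VEGF receptor gene Kdr 1.72-fold lower, while Erg rose 2.89-fold and Aqp1, encoding a water channel, rose 1.95-fold to 16510 ± 1178 normalised read counts (SD, n = 4). The endothelial call was lost without any 1 of sham replicates 1 and 3 and injury replicate 2, with adjusted p of 0.0326 to 0.0756 over the 8 fits without 1 library. It was also lost with equal totals (adjusted p = 0.104) and with the muscle covariate (adjusted p = 0.0867), in a range of 0.0255 to 0.577 over all alternatives, and under that covariate 6 members fell and Kdr lost its call (log2 fold change −0.40, from −0.79). Of 13 pericyte and smooth muscle genes, 2 rose, 7 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.163, and adjusted p = 0.672 with an estimated correlation); Des, encoding the muscle filament desmin, was 7.07-fold lower beside a muscle share of 9.90% in sham and 1.52% in injured tendon. The count of 7 became 4 without any 1 of sham replicates 1 and 2 and injury replicates 1 and 2, and 0 with the muscle covariate, which turned the list's median to 0.21. Des is itself a gene of that covariate. Without sham replicate 4 and injury replicates 3 and 4 together 1 rose, 11 fell and that list passed (adjusted p = 0.0119, in a range of 0.0119 to 0.672 over all alternatives).

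Of 16 Schwann cell and nerve genes, 2 rose, 7 fell and 7 did not pass (8 fell adjusted over the list alone; camera adjusted p = 0.201, and adjusted p = 0.675 with an estimated correlation). S100b was 2.32-fold lower and Gap43, a gene of growing axons, rose 2.64-fold; the count of 7 became 4 without any 1 of sham replicates 1 and 2 and injury replicate 1, and 0 with the muscle covariate, which turned the median to 0.23. In that fit S100b lost its call although its log2 fold change was no smaller (−1.37, from −1.21). Without sham replicate 4 and injury replicates 3 and 4 together 12 members fell and the Schwann cell list passed (adjusted p = 0.0182, in a range of 0.0182 to 0.675 over all alternatives). Among 10 genes of nerve ingrowth and pain, 1 rose, 3 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.26, and adjusted p = 0.577 with an estimated correlation). The gene that rose was Tac1, which encodes substance P, from 14.5 ± 5.26 to 95 ± 20.1 normalised read counts (6.45-fold), while the CGRP receptor component Ramp1 was 2.77-fold lower, or 1.61-fold and not called with the muscle covariate. The 3 that fell became 0 in that fit, and 5 with equal totals or without sham replicate 4 and injury replicates 3 and 4 together. Of 17 myofibroblast and contractile genes, 9 rose, 5 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.465 with an estimated correlation). Cdh11, a fibroblast cadherin gene, rose 13.6-fold and Itga11, a collagen receptor gene, rose 5.68-fold, whereas Tpm2, a tropomyosin gene also expressed in skeletal muscle, was 8.09-fold lower, beside the same muscle shares, and lost its call with the muscle covariate (log2 fold change −0.56, from −3.02). The 5 that fell became 0 in that fit and 8 without sham replicate 4 and injury replicates 3 and 4 together. That list was not called without injury replicate 4 (adjusted p = 0.0523) or with the replicate number as a block (adjusted p = 0.0651). Nor was it called without sham replicate 4 and injury replicates 3 and 4 together (adjusted p = 0.206). Its adjusted p over all alternatives was 3.64e-06 to 0.465.

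Of 28 immediate early and stress genes, 15 rose, 3 fell and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.613 with an estimated correlation), with Nr4a2 up 8.76-fold and the heat shock gene Hspb1 3.45-fold lower. The call was lost without sham replicate 3 (adjusted p = 0.0698), without injury replicate 2 (adjusted p = 0.0669) and with the muscle covariate (adjusted p = 0.0867), in a range of 0.00559 to 0.613 over all alternatives. In the fit with the covariate its median was 0.39, from 0.45, and 4 genes rose and 1 fell. Of 22 interferon response genes, 3 rose, 3 fell and 16 did not pass (0 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.694, and adjusted p = 0.908 with an estimated correlation). The 3 interferon genes that rose became 5 without sham replicate 3 or injury replicate 1, and 1 with equal totals or without sham replicate 4 and injury replicates 3 and 4 together. The 3 that fell became 6 without sham replicate 4, 5 without sham replicate 4 and injury replicates 3 and 4 together, and 1 with the muscle covariate or without any 1 of sham replicates 1 and 2 and injury replicates 1 and 3. None of 6 mast cell genes passed, in limma over all genes or adjusted over the list alone (camera adjusted p = 0.793, and adjusted p = 0.922 with an estimated correlation). Of 13 genes of synovium and the tissue around tendon, 7 rose, 3 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0585, and adjusted p = 0.541 with an estimated correlation), with Pi16 up 4.34-fold. That list passed without sham replicate 1 (adjusted p = 0.0413; only 1 gene then fell), without injury replicate 2 (adjusted p = 0.0451), with equal totals (adjusted p = 0.0262) and with the muscle covariate (adjusted p = 0.0237; again only 1 fell), in a range of 0.000593 to 0.541 over all alternatives. Of 7 keratinocyte genes, 2 rose, 2 fell and 3 did not pass (2 and 4 adjusted over the list alone; camera adjusted p = 0.572, and adjusted p = 0.653 with an estimated correlation). The 2 keratinocyte genes that rose became 1 without any 1 of sham replicate 2 and injury replicates 2 and 3, with the muscle covariate or without sham replicate 4 and injury replicates 3 and 4 together, and the 2 that fell became 1 with the muscle covariate or without any 1 of sham replicates 1, 2 and 3 and injury replicates 2 and 4. Of 32 ribosomal protein genes, 1 rose, 4 fell and 27 did not pass, and 0 passed adjusted over the list alone (camera adjusted p = 0.0939, and adjusted p = 0.702 with an estimated correlation). The ribosomal list passed without sham replicate 4 (adjusted p = 0.038), without injury replicate 1 (adjusted p = 0.0367) and with the muscle covariate (adjusted p = 4.52e-05), in a range of 4.52e-05 to 0.702 over all alternatives. Its 4 genes that fell became 7 without sham replicate 4 or with the muscle covariate, 0 without sham replicate 4 and injury replicates 3 and 4 together, 2 without sham replicate 1 or injury replicate 2, and 1 without any 1 of sham replicates 2 and 3 and injury replicates 3 and 4. Its 1 gene that rose became 0 without any 1 of sham replicate 2 and injury replicates 1, 3 and 4, and with equal totals, with the muscle covariate or without sham replicate 4 and injury replicates 3 and 4 together. Neutrophil, T cell and B cell lists had too few measured members to test (3, 4 and 4). Of these, 2, 2 and 2 rose and 1, 1 and 0 fell, or 1, 2 and 1 and 1, 0 and 0 with the muscle covariate, and 1 B cell gene fell without sham replicate 4 and injury replicates 3 and 4 together. Among them Il7r rose 5.02-fold, from 33.2 ± 9.43 to 169 ± 33.3, and Lcn2 was 2.92-fold lower.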
